A study of Arabidopsis thaliana with 12 samples.

How the data were processed

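Gene expression was measured in hypocotyls of Arabidopsis thaliana, ecotype Col-0, on 12 Affymetrix arrays, 3 in each of 4 groups. Per the labels, the plants were 7 or 35 days old, had grown on full-strength MS medium, and had received no auxin or auxin for 1 day. The labels name neither the auxin, its dose nor the medium of the treatment, and they do not say whether the untreated hypocotyls were kept for the same day. Total RNA was purified on RNeasy columns after DNase treatment, and biotin-labelled cRNA was made from 10 ug of it. The arrays of a group are described as biological replicates. Each p rests on the spread between replicates within groups, pooled over the 12 arrays, and the 3 arrays per group limit the precision.

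The authors computed expression values with RMA, which corrects background, normalises the arrays to a common distribution and summarises each probe set. The deposited values are RMA values on a log scale, read here as log2 because RMA gives log2 values; neither the base nor the software version is stated. In the deposited table each probe set is centred on its median over the 12 arrays: that median is 0 in all 22810 rows, to 5 decimals. Differences between arrays are kept, but absolute levels are not, so no statement is made on which genes were strongly or weakly expressed, and no filter on dim probe sets was possible. The values run from −6.64 to 6.77. All 12 columns belong to a known array.

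Of the 22810 probe sets, 64 are controls and were left out of the tests, which leaves 22746. By the annotation of the array used here, 13513 of these have 1 gene, 503 have several and 8730 are listed with none. The 13513 cover 13355 genes, 147 of them with more than 1 probe set. A probe set with several genes, or with none, was counted but never named.

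Differences were tested with limma (version 3.58.1, R version 4.3.3). One linear model with the 4 groups was fitted to all 12 arrays, with 8 residual degrees of freedom and an empirical Bayes estimate of the spread. The contrasts were auxin in young (7-day) hypocotyls, auxin in mature (35-day) hypocotyls, age without auxin, age with auxin, and the difference of the auxin response between ages. Age contrasts are mature minus young, and the last contrast is the mature minus the young response. Tests were two-sided, p was adjusted by the Benjamini-Hochberg method over the 22746 probe sets, and a probe set was called at an adjusted p under 0.05 with no minimum fold. Errors beside log2 fold changes are standard errors (SE) of the contrast from this fit. The mature was compared with the young response by the first principal axis through the origin (total least squares) over probe sets called at either age, with no p because genes are not independent replicates.

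Before the data were examined, 38 gene lists with 545 genes were fixed, of which 86 genes have a probe set of their own on the array as annotated here, and 17 lists have the 3 measured genes that were required for a test. The other lists have fewer and were not tested. A further 36 lists, 35 of them large enough to test, were written after the annotation was seen and before any expression value of their genes; these are called added lists below. Lists were tested with camera from limma, which compares a list with all other genes, at a preset correlation between genes of 0.01, on 1 value per gene, with p adjusted over the fixed and over the added lists separately. The plan was to take the probe set with the highest mean for a gene. Centring removes that mean, so the average of a gene's probe sets was used instead. Counts of genes that rose or fell in a list come from a limma fit of these 13355 genes, and values of single genes come from the fit of the probe sets. Camera with an estimated correlation and fry, which asks whether the genes of a list move one way on balance, were run as alternatives. The limma fit and the list tests were tried on simulated data with known changes in the young group with auxin.

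The genes named below follow a rule fixed at the same time as the 38 lists. It takes, for each contrast, the 5 largest called rises and the 5 largest called falls among probe sets with 1 named gene whose groups do not overlap, up to 2 rises and 2 falls in each list in the contrasts the list was meant for, and 8 genes in every contrast, of which GH3.3, LBD16 and LBD29 are the 3 measured here. It gave 556 results for 276 genes. Genes are given by the symbol of the annotation, or by locus where it has none.

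Whether the replicate numbers of the labels pair the arrays was checked by the correlation of their deviations from the group means. Between the 2 auxin groups all 3 same-numbered pairs lay above 0.1 (0.250, 0.158 and 0.122), and in no other pair of groups did all 3. The numbers pair these arrays by that measure alone. Deviations within a group sum to 0, so the 3 values are not independent, and every pair of groups was checked. The fit without a block stayed the main one, as planned.

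Alternatives covered the scaling of the arrays, a replicate block, array weights, a robust spread estimate, fits of 2 groups alone, other thresholds and leaving out each array. Terms and subsets for the arrays with a low bioC spike-in signal, described with the data, were chosen after seeing the data. Quantile normalisation again, filters on dim probe sets and an intensity trend of the spread need absolute levels and were not run. Figures and tables were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.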

Results

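Expression was measured on 22746 non-control probe sets in young (7-day) and mature (35-day) hypocotyls, the seedling stems of Arabidopsis, without auxin and after 1 day of auxin, on 12 arrays, 3 in each of the 4 groups. The series concerns how the capacity to form callus, the dividing tissue that auxin induces, changes with age. Arrays of one group resembled each other: their Pearson correlations across probe sets lay between 0.910 and 0.964, and those between groups between −0.79 and 0.56 (probe sets are not independent replicates). The first principal component held 68.3% of the variance and the second 22.2%.

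Control probe sets set some arrays apart. The bioC spike-in, a control made from a bacterial transcript, lay between −1.43 and −1.61 (log2, relative to its median) on arrays 1 and 2 of both untreated groups. It lay at 0.70 and 0.48 on array 3 of these groups, and between −0.20 and 0.20 on the 6 auxin arrays. The 25S ribosomal RNA control was higher with auxin, by 4.19 ± 0.44 (SE) in young and 3.12 ± 0.44 in mature hypocotyls on the log2 scale. It lay between −2.56 and −2.19 on the 4 arrays of low bioC signal, and at −1.06 on array 3 of both untreated groups. The rise is thus smaller against array 3 alone. GAPDH, whose 3′ and 5′ probe sets can report RNA integrity, had a 3′ excess, relative to the probe set medians, of 0.33 to 0.51 in the young untreated arrays, and of at most 0.21 on the others. Its group mean was 0.40 without and −0.09 with auxin in young hypocotyls, and 0.17 and −0.15 in mature ones. Other pairs were mixed. Actin gave −0.07 without and −0.06 with auxin in young hypocotyls, and 0.02 and −0.16 in mature ones. Ubiquitin gave 0.02 and −0.06, and 0.08 and 0.03. With auxin in young hypocotyls, the 3′ and 5′ probe sets of second pairs changed by 0.84 and 0.77 (GAPDH), 0.25 and 0.44 (actin), and −0.17 and 0.01 (ubiquitin). A difference in RNA integrity is thus not settled by GAPDH. The mean of the cre spike-ins was 0.16 without and −0.35 with auxin in young, and 0.23 and −0.31 in mature hypocotyls. Another Arabidopsis control probe set differed with auxin by −1.77 ± 0.79 (SE) in young and −3.45 ± 0.79 in mature hypocotyls; it lay between −0.08 and 4.09 on untreated arrays and between −0.41 and 0.08 on auxin arrays. Results without the 4 arrays of low bioC signal therefore stand beside each comparison that uses them; these subsets were chosen after seeing the data.

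**Figure D1:**
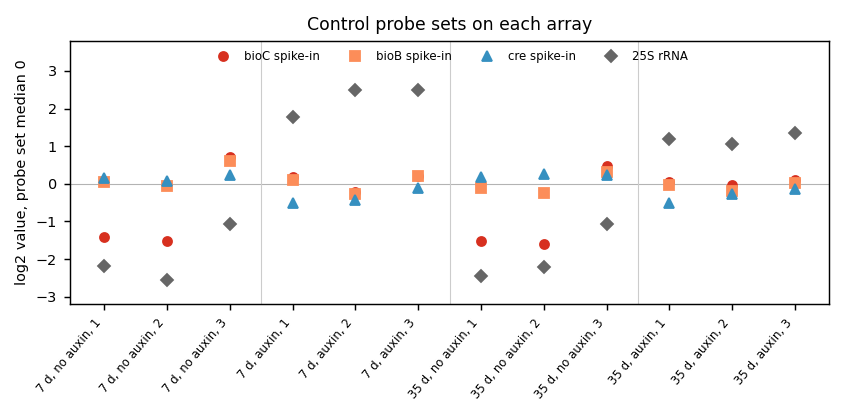
Log2 values of 4 kinds of control probe sets on each of the 12 arrays, each relative to its median. The bioC spike-in is low on 4 untreated arrays, and the 25S rRNA signal is positive on the 6 auxin arrays alone.

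The first question was what auxin changes in young hypocotyls. Single genes of auxin inactivation and lateral root initiation rose many-fold, though neither list was called, and genes of photosynthesis fell (adjusted p = 0.236 for that list with an estimated correlation). GH3.1, which encodes an enzyme that conjugates auxin to amino acids, was 202-fold higher (log2 fold change 7.66 ± 0.10 SE, n = 3 per group, limma adjusted p = 3.3e-14), and the related GH3.3 was 27.2-fold higher (4.76 ± 0.25). LBD29 and LBD16, transcription factors of lateral root initiation and callus formation, were 80.3-fold (6.33 ± 0.12) and 24.1-fold higher (4.59 ± 0.11). PSAN, a subunit of photosystem I, was 302-fold lower (−8.24 ± 0.23), LHCB4.2, a light-harvesting antenna protein, 209-fold lower (−7.71 ± 0.20), and PRK, a kinase of the Calvin cycle, 125-fold lower (−6.97 ± 0.16).

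The largest rises were those of AT2G19970 (321-fold, 8.33 ± 0.18) and PR-1-LIKE (316.5-fold, 8.31 ± 0.15), followed by GH3.1, AT1G64405 and the class III peroxidase gene AT2G18980 (119.1-fold, 6.90 ± 0.21). Of the 6 measured genes of auxin inactivation, 4 rose and 1 fell, with the same counts adjusted over the list alone; the list missed its threshold (camera adjusted p = 0.05004), at an adjusted p = 0.236 with an estimated correlation. Of 4 measured genes of lateral root initiation 3 rose, also adjusted over the list alone, among them PUCHI, a transcription factor (28.3-fold, 4.82 ± 0.27); this list too missed its threshold (camera adjusted p = 0.05004, and adjusted p = 0.246 with an estimated correlation). Of 7 measured AUX/IAA genes, which encode repressors of the auxin response, 4 rose and 0 fell, with the same counts adjusted over the list alone. IAA30 was 7.77-fold higher (2.96 ± 0.12) and IAA29 6.48-fold higher (2.70 ± 0.13), and the list was not called (camera adjusted p = 0.104, and adjusted p = 0.436 with an estimated correlation).

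All 6 measured genes of the fixed photosynthesis list fell, also adjusted over the list alone, with a median of −6.24 (camera adjusted p = 1.4e-06; adjusted p = 0.236 with an estimated correlation). In the added list of photosynthesis and photorespiration 15 of 15 genes fell, with a median of −6.08, and so did 62 of 69 plastid-encoded genes, with a median of −1.23, such as psbB (−2.93 ± 0.36) of photosystem II. All 5 measured genes of chlorophyll synthesis fell, among them CHLM (45.4-fold lower, −5.50 ± 0.13) and PORB (35.9-fold lower, −5.17 ± 0.17). These 3 lists were called (camera adjusted p = 3e-14, 1.5e-11 and 1.5e-04), at an adjusted p = 0.286, 0.709 and 0.286 with an estimated correlation. The sugar transporter genes SWEET11 (48.1-fold lower, −5.59 ± 0.19) and SWEET2 (20.8-fold lower, −4.38 ± 0.23) fell as well, while their family of 16 had 4 rises and 6 falls and was not called (camera adjusted p = 0.38, and adjusted p = 0.833 with an estimated correlation).

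Of 115 measured genes of cytosolic ribosomal proteins 113 rose, and AT5G59240 rose the most (27.1-fold, 4.76 ± 0.14). All 12 genes of RNA polymerase subunits rose, such as NRPA1, the largest subunit of RNA polymerase I (2.77-fold, 1.47 ± 0.09). All 6 measured DNA replication genes rose, such as the helicase gene PRL, also known as MCM7 (2.34-fold, 1.23 ± 0.12), and so did 8 of 9 core histone genes. Of 18 measured genes of the G2 phase and mitosis 14 rose and 1 fell, with a median of 0.75; AUR1, an Aurora kinase, was 2.03-fold higher (1.02 ± 0.10) and AT5G16250 1.79-fold lower (−0.84 ± 0.10). These 5 added lists were called (camera adjusted p between 2.7e-25 and 0.0122), at an adjusted p = 0.388, 0.286, 0.388, 0.741 and 0.741 with an estimated correlation. Of 3 measured genes of ribosome biogenesis 2 rose and 1 fell, as also adjusted over the list alone, and the list was not called (camera adjusted p = 0.28).

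Cell wall genes moved both ways. The xyloglucan-modifying enzyme genes XTH19 (20.4-fold, 4.35 ± 0.29) and XTH18 (18.7-fold, 4.23 ± 0.17) rose and XTH32 fell (−3.51 ± 0.17). Of 7 measured expansins, proteins that loosen walls, 3 rose and 3 fell, also adjusted over the list alone; EXPA4 was 4.66-fold higher (2.22 ± 0.14) and EXPA8 11.9-fold lower (−3.57 ± 0.21). The suberin list, made of 4 GDSL lipase genes and FACT, a caffeoyl transferase, had 5 rises of 5 with a median of 3.64 (camera adjusted p = 0.0181; adjusted p = 0.574 with an estimated correlation). CLE44, which encodes a peptide that acts on the vascular cambium, was 42.4-fold higher (5.40 ± 0.10). Of 11 autophagy genes 8 fell and 1 rose (camera adjusted p = 0.0139; adjusted p = 0.741 with an estimated correlation). The 3 senescence genes of the fixed list rose, also adjusted over the list alone, with a median of 2.82 (camera adjusted p = 0.0562). The 2 measured genes of the cytokinin response fell, RR16, also known as ARR16 (6.64-fold lower, −2.73 ± 0.22), and ARR15 (−1.13 ± 0.17); this list was too short for a test.

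In all, limma called 13440 of 22746 probe sets (59.1%), 7441 higher and 5999 lower with auxin; 5663 of them differed 2-fold or more. In 14661 probe sets no array of one group overlapped the other, which chance gives in 10%. The treatment moved with the control signals given above. Without the 4 arrays of low bioC signal 11428 probe sets were called, 11141 of them among the 13440. Of the 13440, 13437 kept the sign of their fold change, although each untreated group then held 1 array, assumed to vary like the other groups. The 13440 were selected on arrays that this fit reuses, so keeping the sign is partly built in. Of 17 fixed lists 1 was called, and of 35 added lists 10. The fixed count is unstable: it was 1 without array 2 of the young or arrays 1 or 2 of the mature group with auxin, 2 to 4 without any other single array, and 4 with stable reference genes set equal. With an estimated correlation camera called 0 of either, with 3 and 4 at an unadjusted p under 0.05, and fry called 13 and 29.

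**Figure D2:**
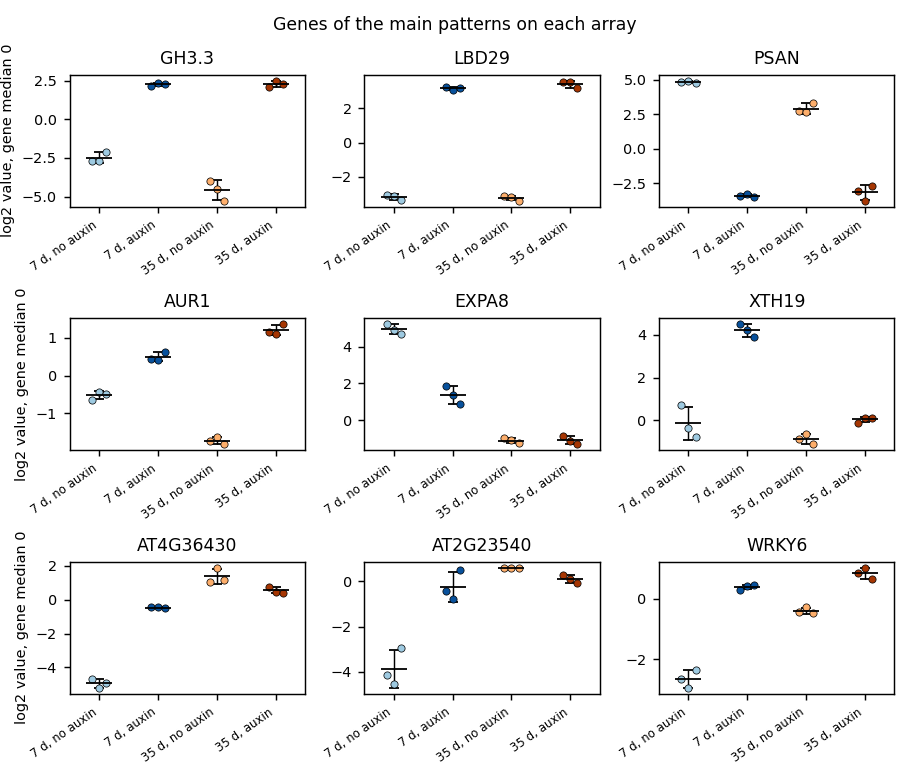
Values of 9 named genes on the 12 arrays in 4 groups (log2, each gene relative to its median over all arrays). Points are arrays, and the bars give the mean and the SD of 3 arrays. PSAN is lower with auxin at both ages, and EXPA8 and AT4G36430 differ between ages mainly without auxin.

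The next question was what auxin changes in mature hypocotyls. The same marker genes rose: GH3.1 was 228-fold higher (7.83 ± 0.10, n = 3 per group, limma adjusted p = 2.4e-14), GH3.3 117.5-fold (6.88 ± 0.25), LBD29 99.2-fold (6.63 ± 0.12), PUCHI 40.2-fold (5.33 ± 0.27) and LBD16 18.8-fold (4.23 ± 0.11). AT1G67750, a pectate lyase gene, was 72.9-fold higher (6.19 ± 0.16) and PR-1-LIKE 69.1-fold (6.11 ± 0.15). HIS1-3, which encodes a linker histone induced by drought, was 98.2-fold lower (−6.62 ± 0.10). AT1G62510 (−6.55 ± 0.23), CCL (−6.47 ± 0.18) and AT2G15960 (−6.29 ± 0.18) fell by similar amounts, and LHCB4.2 was 69.0-fold lower (−6.11 ± 0.20).

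All 4 measured genes of lateral root initiation rose, also adjusted over the list alone, with a median of 4.78 (camera adjusted p = 0.00578; adjusted p = 0.267 with an estimated correlation). Of the 6 genes of auxin inactivation 3 rose and 2 fell, and of the 7 AUX/IAA genes 4 rose and 1 fell, with the same counts adjusted over each list alone. Neither list was called (camera adjusted p = 0.195 and 0.0953). IAA29 was 7.51-fold higher (2.91 ± 0.13).

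The 3 measured genes of the fixed list of G2/M and cytokinesis, the Aurora kinase genes, rose, also adjusted over the list alone, with a median of 2.36 (camera adjusted p = 0.0138; adjusted p = 0.296 with an estimated correlation). AUR1 was 7.64-fold higher (2.93 ± 0.10) and AUR2 5.13-fold (2.36 ± 0.11). In the added list 18 of 18 genes rose, with a median of 2.21. The 6 DNA replication genes rose with a median of 1.81, among them PRL (6.58-fold, 2.72 ± 0.12), ICU2, the catalytic subunit of DNA polymerase alpha (4.17-fold, 2.06 ± 0.13), and POLA3 (5.47-fold, 2.45 ± 0.10). Of the ribosomal protein genes 113 of 115 rose, with a median of 1.44, as did 12 of 12 RNA polymerase genes and 8 of 9 core histone genes. These 5 added lists were called (camera adjusted p between 4.5e-28 and 0.00669), at an adjusted p = 0.212 for the first 4 and 0.525 for the histones with an estimated correlation.

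The 6 photosynthesis genes of the fixed list fell, also adjusted over the list alone, with a median of −4.74 (camera adjusted p = 5.6e-06; adjusted p = 0.267 with an estimated correlation). In the added lists 14 of 15 genes of photosynthesis, 57 of 69 plastid-encoded genes and 5 of 5 genes of chlorophyll synthesis fell (camera adjusted p = 9.7e-12, 2e-10 and 0.00216), at an adjusted p = 0.212, 0.525 and 0.266 with an estimated correlation. Of 11 autophagy genes 10 fell, of 13 glutathione S-transferase genes 8 fell and 2 rose, and of 16 mitochondrion-encoded genes 10 fell and 1 rose. These lists were called as well (camera adjusted p = 4.0e-04, 0.00584 and 0.00332), at an adjusted p = 0.437, 0.212 and 0.286 with an estimated correlation. GSTU26 was 10.5-fold lower (−3.39 ± 0.12), yet GSTU25 21.9-fold higher (4.45 ± 0.14). In the whole expansin family 9 of 14 genes rose and 0 fell, such as EXPB2 (6.49-fold, 2.70 ± 0.15) and EXPA15 (1.76 ± 0.12), a call (camera adjusted p = 0.0362; adjusted p = 0.522 with an estimated correlation) that ended without array 1 of the untreated mature group (adjusted p = 0.0586), without array 2 of the mature group with auxin (0.0564) and without the 4 arrays of low bioC signal (0.0615). PDF1.4, a defensin gene, was 12.1-fold lower (−3.60 ± 0.10). Of the 7 fixed expansins 5 rose and 0 fell, and of the 3 glucosinolate genes 3 fell, also adjusted over each list alone; neither list was called (camera adjusted p = 0.195 and 0.144).

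Limma called 13632 probe sets (59.9%), 7235 higher and 6397 lower (6632 and 6753 with array medians set equal); 5475 differed 2-fold or more, and in 14669 the groups did not overlap, against 10% by chance. The control signals given above moved with this treatment too, and without the 4 arrays of low bioC signal 11514 probe sets were called, 11278 of them among the 13632. Of 17 fixed lists 3 were called, and of 35 added lists 12. With an estimated correlation camera called 0, with 2 and 6 at an unadjusted p under 0.05, and fry called 14 and 29.

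Most probe sets that auxin changed in young hypocotyls changed in the same direction in mature ones, but many differed in size. Of the 7441 probe sets that rose in young hypocotyls, 5486 (73.7%) also rose in mature ones, against 2367 for independent lists, and of the 5999 that fell 4573 (76.2%) also fell, against 1687. The total was 10059 shared calls, of which 4001 had a called difference in size between ages. Of the 2647 probe sets called in young hypocotyls alone 1666 had a called difference, and of the 2839 called in mature ones alone 1487. Over the 16279 probe sets called at either age, the slope of the mature on the young response was 0.876 (jackknife SD 0.0259). Pearson's r across probe sets was 0.811. The absolute log2 fold change was larger in young hypocotyls in 7992 of these and in mature ones in 8287, with medians of 0.680 and 0.670. The slope thus does not show a weaker mature response in most probe sets. The slope was 0.921 without the 4 arrays of low bioC signal. In 734 probe sets the calls went in opposite directions.

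**Figure D3:**
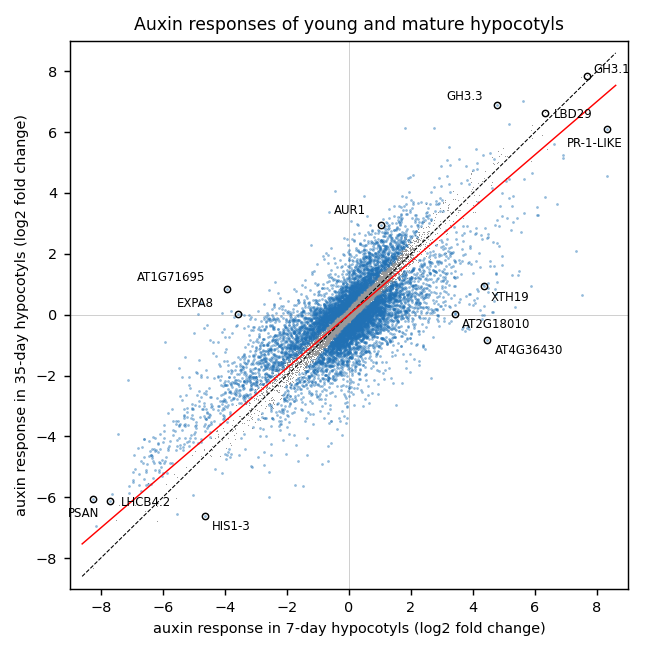
Log2 fold change with auxin in mature (vertical) against young hypocotyls (horizontal) for 22746 probe sets. Blue points have a called difference between ages, the dashed line marks equal responses, the red line has the slope of 0.876, and circles mark 13 named genes.

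The age comparison without auxin asked how mature and young hypocotyls differ before the treatment. Genes of photosynthesis were lower in mature hypocotyls, and genes of suberin and senescence were higher, list calls that are lost with an estimated correlation (adjusted p = 0.3, 0.215 and 0.279). EXPA8 was 66.2-fold lower (−6.05 ± 0.21, n = 3 per group, limma adjusted p = 8.6e-11), AT3G16370 95.8-fold lower (−6.58 ± 0.17) and AT1G12080 72.5-fold lower (−6.18 ± 0.18). The class III peroxidase gene AT4G36430 was 79.4-fold higher (6.31 ± 0.19), OSM34, an osmotin-like defence gene, 43.4-fold (5.44 ± 0.23), and AT4G16260, a glucanase gene, 31.6-fold (4.98 ± 0.29). FACT (24.6-fold, 4.62 ± 0.11) and AT2G23540 (4.46 ± 0.35) of the suberin list were higher too.

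AT2G18370 (48.8-fold, 5.61 ± 0.24) and AT3G58550 (47.0-fold, 5.55 ± 0.11) completed the largest rises, and AT2G10940 (−6.29 ± 0.34) and AT1G09750 (−5.81 ± 0.24) the largest falls. All 5 genes of the suberin list rose with age, with a median of 3.16 (camera adjusted p = 1.9e-05; adjusted p = 0.215 with an estimated correlation). PDF1.4 was 21.6-fold higher (4.43 ± 0.10) and GRX480, a glutaredoxin gene of the salicylate response, 4.55-fold (2.18 ± 0.18); their defence list of 5 had 2 rises and 1 fall and was not called (camera adjusted p = 0.168). STZ, also known as ZAT10, a stress-induced zinc finger gene and the one measured member of its list, was higher (1.67 ± 0.26).

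In the fixed lists, 3 of 3 genes rose for senescence (median 1.73), for cambium regulators (1.18) and for glucosinolate synthesis (1.32), with the same counts adjusted over each list alone. These were WRKY6 (4.71-fold, 2.24 ± 0.13) and WRKY53 (3.32-fold, 1.73 ± 0.17), transcription factors of leaf senescence, and SAG101. They were also CLE44 (4.86-fold, 2.28 ± 0.10), CLE41 (2.27-fold, 1.18 ± 0.11) and the receptor kinase gene MOL1, and BCAT4 (20.7-fold, 4.37 ± 0.38), UGT74B1 (2.49-fold, 1.32 ± 0.15) and AT2G31790, also known as UGT74C1. Their camera adjusted p was 0.00435, 0.0106 and 0.0127, against an adjusted p = 0.279, 0.279 and 0.3 with an estimated correlation. SAG101, MOL1 and UGT74C1 are named here after their values were seen.

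The 6 photosynthesis genes and the 3 Aurora kinase genes fell with age, also adjusted over each list alone, with medians of −1.48 and −1.21 (camera adjusted p = 9.4e-04 and 0.0106; adjusted p = 0.3 and 0.279 with an estimated correlation). PSAN was 3.78-fold lower (−1.92 ± 0.23) and AUR2 2.43-fold lower (−1.28 ± 0.11). In the added lists 14 of 15 photosynthesis genes, 5 of 5 genes of chlorophyll synthesis, 26 of 69 plastid-encoded genes (1 rose), 13 of 18 G2/M genes and 8 of 15 IQD genes (1 rose) fell. These were called (camera adjusted p = 5e-08, 8.8e-04, 8.8e-04, 3.3e-05 and 0.0104), at an adjusted p = 0.215, 0.215, 0.727, 0.37 and 0.215 with an estimated correlation; fry did not call the plastid-encoded list (adjusted p = 0.0614). Higher in mature hypocotyls were 7 of 11 autophagy genes and 11 of 16 mitochondrion-encoded genes (1 fell), such as nad9 (2.71-fold, 1.44 ± 0.12), and 7 of 13 glutathione S-transferase genes (2 fell), such as GSTU15 (3.75-fold, 1.90 ± 0.12). These lists too were called (camera adjusted p = 0.0112, 3.2e-04 and 0.0186; adjusted p = 0.499, 0.215 and 0.215 with an estimated correlation).

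Of 22 beta-glucosidase genes 10 rose and 2 fell, of 51 UDP-glycosyltransferase genes 17 rose and 9 fell, of 8 calmodulin-like genes 5 rose and 1 fell, and of 12 nitrate and peptide transporter genes 5 rose and 1 fell. Camera called these 4 lists (adjusted p = 0.0122, 0.0414, 0.0402 and 0.0402), at an adjusted p = 0.37, 0.528, 0.37 and 0.215 with an estimated correlation. Without single untreated arrays the calls of the glycosyltransferase (adjusted p up to 0.0633), calmodulin-like (up to 0.0527) and transporter lists (0.0501) ended, and the first 2 also ended without the 4 arrays of low bioC signal (0.124 each). The arrays were 1 and 2 of the young and 1 of the mature group, 2 and 3 of the young group, and 2 of the young group. GTR2, a glucosinolate transporter gene, was 3.73-fold higher (1.90 ± 0.08) and CML41 5.43-fold (2.44 ± 0.17). XTH32 (8.23-fold lower, −3.04 ± 0.17) and EXPA16 (3.37-fold lower, −1.75 ± 0.12) fell with age. GH3.3 was 4.25-fold lower in mature hypocotyls (−2.09 ± 0.25) and RR16 4.54-fold lower (−2.18 ± 0.22), whereas LBD16 (0.27 ± 0.11, adjusted p = 0.0588) and LBD29 (−0.06 ± 0.12, adjusted p = 0.732) did not pass the test. On arrays 1 to 3, GH3.3 lay at −2.68, −2.70 and −2.09 in young and at −3.97, −4.49 and −5.27 in mature hypocotyls. The ages thus differed most on array 3, of usual bioC signal. SNZ, a repressor of flowering, was 4.32-fold lower (−2.11 ± 0.08) and AGL24, a promoter of it, 1.82-fold higher (0.86 ± 0.12), in a list of 3 that was not called (camera adjusted p = 0.876).

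Limma called 10386 probe sets (45.7%), 5171 higher and 5215 lower in mature hypocotyls; 3056 differed 2-fold or more, and in 12144 the groups did not overlap, against 10% by chance. Each group held 2 arrays of low and 1 of usual bioC signal. Within the low set and within the usual set, 10325 of the 10386 fold changes had the same sign, with a slope between the sets of 0.859. The 10386 were called on both sets together, so part of this agreement is built in. The 1 array per group of usual signal gave 5574 calls, 5461 of them among the 10386. The 3′ excess of GAPDH given above was highest in the young untreated group, but that of actin and of ubiquitin was highest in the mature untreated group. The 3′ and 5′ probe sets of the second pairs differed with age by 0.45 and 0.49 (GAPDH), 0.16 and 0.28 (actin), and 0.35 and 0.22 (ubiquitin). Of 17 fixed lists 5 were called, and of 35 added lists 13; with an estimated correlation camera called 0, with 3 and 7 at an unadjusted p under 0.05, and fry called 11 and 23.

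The age comparison with auxin asked how mature and young hypocotyls differ after the treatment. OSM34 (37.0-fold, 5.21 ± 0.23, n = 3 per group, limma) and AT4G16260 (4.33 ± 0.29) stayed higher in mature hypocotyls, as did FACT (14.2-fold, 3.83 ± 0.11), AT1G14120 (20.6-fold, 4.37 ± 0.19), AT1G10585 (4.26 ± 0.25) and AT3G58550 (4.25 ± 0.11). AT2G18010, a gene of the SAUR family of early auxin response genes, was 29.8-fold lower (−4.90 ± 0.20), XTH19 18.0-fold lower (−4.17 ± 0.29) and AT1G29660, a GDSL lipase gene, 33.5-fold lower (−5.07 ± 0.17). AT2G10940 (−4.89 ± 0.34), AT2G14900 (−4.59 ± 0.16) and AT4G16980 (−4.57 ± 0.29, a gene with more than 1 probe set) were the other largest falls. The auxin markers did not pass the test: GH3.3 differed by 0.03 ± 0.25 (adjusted p = 0.96), LBD16 by −0.09 ± 0.11 (adjusted p = 0.62) and LBD29 by 0.25 ± 0.12 (adjusted p = 0.154).

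Genes of mitosis were higher and genes of the xylem wall lower in mature hypocotyls with auxin, list calls that are lost with an estimated correlation (adjusted p = 0.256 and 0.146 for the added lists). Of the 18 G2/M genes 17 were higher, with a median of 0.76, such as AT1G63100 (2.25-fold, 1.17 ± 0.18), and the 3 Aurora kinase genes of the fixed list were higher with a median of 0.71, also adjusted over the list alone; AUR1 was 1.63-fold higher (0.71 ± 0.10). Camera called both (adjusted p = 1.1e-09 and 0.0316), at an adjusted p = 0.256 and 0.663 with an estimated correlation, and the fixed list lost its call without array 1 of the young (adjusted p = 0.0562) or array 3 of the mature group with auxin (0.071). Of the 15 genes of xylem and secondary wall 14 were lower, with a median of −1.16 (camera adjusted p = 4.7e-12; adjusted p = 0.146 with an estimated correlation), such as GUT2, also known as IRX10, a xylan synthase gene (2.14-fold lower, −1.10 ± 0.11), and AT5G40020 (4.59-fold lower, −2.20 ± 0.21).

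Of 23 trichome birefringence-like genes, which act in wall acetylation, 10 were lower and 1 higher, of 10 XTH genes 5 were lower and 1 higher, of 15 IQD genes 9 were lower and 1 higher, and of 69 plastid-encoded genes 15 were lower. These 4 lists were called (camera adjusted p = 0.00303, 0.00525, 8.7e-04 and 7.8e-04), at an adjusted p = 0.146, 0.407, 0.146 and 0.665 with an estimated correlation. Of 22 beta-glucosidase genes 9 were higher and 1 lower, and of 115 ribosomal protein genes 8 were higher and 1 lower, with a median of 0.10 (camera adjusted p = 0.00854 and 0.0121; adjusted p = 0.407 and 0.708 with an estimated correlation). The ribosomal protein list lost its call without array 1 of the young group (adjusted p = 0.195), without array 3 of the mature group (0.114) and with fry (0.115), and fry did not call the plastid-encoded list either (adjusted p = 0.192). Of the 15 photosynthesis genes 3 were higher and 0 lower, and that list was not called (camera adjusted p = 0.0657). EXPA8 (−2.46 ± 0.21) and EXPA9 (3.85-fold lower, −1.94 ± 0.10) were lower.

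**Figure D4:**
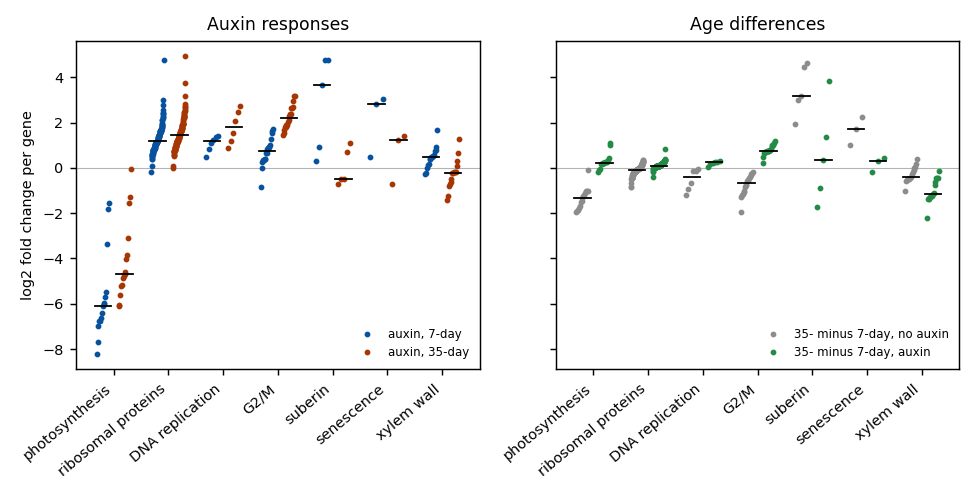
Log2 fold changes of the genes of 7 lists, with auxin (left panel) and between ages (right panel); each point is a gene and each bar the median of its list. The G2/M genes lie below 0 without auxin and above 0 with auxin in the right panel, with medians of −0.66 and 0.76.

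Limma called 6206 probe sets (27.3%), 3239 higher and 2967 lower in mature hypocotyls; 1587 differed 2-fold or more, and in 9255 the groups did not overlap, against 10% by chance. The split between directions depends on the scaling: with the arrays set equal on stable reference genes, 6649 were called, 4400 higher and 2249 lower, and the median of all probe sets moved from 0.03 to 0.11 (from 0.05 to 0.13 for the difference of responses). All 6 arrays of this comparison had a bioC signal in the usual range. Of the 5171 probe sets higher in mature hypocotyls without auxin 1759 (34.0%) were also higher with auxin, and of the 5215 lower ones 1528 (29.3%) were also lower, against 736 and 680 for independent lists. Of 17 fixed lists 1 was called (0 without array 1 of the young or array 3 of the mature group), and of 35 added lists 8; with an estimated correlation camera called 0, with 1 and 4 at an unadjusted p under 0.05, and fry called 9 and 20.

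The last comparison asked where the auxin response itself differed between ages. Mitotic genes responded more in mature hypocotyls, photosynthesis genes fell less there, and suberin and senescence genes responded more in young ones. Camera called these lists at its preset correlation and none of them with an estimated one (adjusted p = 0.152, 0.233, 0.169 and 0.152). Levels without auxin enter these differences. In the fixed lists the median age difference was −1.48 without and 0.29 with auxin for photosynthesis, and 1.73 and 0.32 for senescence. For G2/M and cytokinesis it was −1.21 and 0.71. The genes of the added suberin list were already higher in mature hypocotyls without auxin, by a median of 3.16. A common end level from different starting levels was tested for the added G2/M list alone. AUR1 rose more in mature hypocotyls by 1.92 ± 0.14 on the log2 scale (n = 3 per group, limma), a ratio of responses of 3.77, and AUR2 by 2.02 ± 0.16. GH3.3 (2.11 ± 0.36) and WES1, also known as GH3.5 (1.93 ± 0.23), had larger rises in mature hypocotyls, whereas LBD16 (−0.37 ± 0.16, adjusted p = 0.0884) and LBD29 (0.30 ± 0.17, adjusted p = 0.188) did not pass the test. For GH3.3 the size depends on the untreated arrays. On array 3 it lay at −2.09 in young and −5.27 in mature hypocotyls, further apart than on the arrays of low bioC signal. AT4G36430 rose in young and fell in mature hypocotyls, a difference of −5.30 ± 0.27.

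The largest positive differences were those of AT3G46490 (5.16 ± 0.17), AT1G09750 (5.04 ± 0.34), the peroxidase gene AT1G71695 (4.78 ± 0.14), AT1G12080 (4.53 ± 0.25) and AT5G48490 (4.21 ± 0.42). After AT4G36430 the largest negative ones were AT5G12420 (−4.52 ± 0.37), AT5G57785 (−4.47 ± 0.28), AT4G38080 (−4.33 ± 0.39) and AT1G80130 (−4.31 ± 0.19). All 3 Aurora kinase genes and all 6 photosynthesis genes of the fixed lists had positive differences past the test, also adjusted over each list alone, with medians of 1.92 and 1.69 (camera adjusted p = 6.5e-04 and 8.4e-05; adjusted p = 0.152 and 0.233 with an estimated correlation). For PSAN the difference was 2.18 ± 0.32. The 3 senescence genes had negative differences, also adjusted over the list alone, with a median of −1.41 (camera adjusted p = 0.0022; adjusted p = 0.152 with an estimated correlation). Of the 3 cambium genes 1 was negative, CLE44 (−2.23 ± 0.15), and 2 adjusted over the list alone (camera adjusted p = 0.0351; adjusted p = 0.264 with an estimated correlation). That call ended without array 3 of the untreated young group (adjusted p = 0.0529), arrays 1 or 2 of the untreated mature group (0.0539 and 0.0501) or the 4 arrays of low bioC signal (0.119).

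In the added lists 18 of 18 G2/M genes had a positive difference, with a median of 1.43, as had 14 of 15 photosynthesis genes (1.60), 5 of 5 genes of chlorophyll synthesis (1.01), 3 of 6 DNA replication genes (0.66) and 21 of 115 ribosomal protein genes (0.19). Camera called them (adjusted p = 4.9e-12, 9.7e-11, 5.9e-04, 0.0122 and 0.00208), at an adjusted p = 0.169, 0.169, 0.169, 0.228 and 0.674 with an estimated correlation; fry did not call the ribosomal protein list (adjusted p = 0.0657). Negative differences were found in 5 of 5 suberin genes (median −3.69), 10 of 15 genes of xylem and secondary wall (−0.66), 7 of 13 glutathione S-transferase genes (2 positive), 7 of 16 mitochondrion-encoded genes, 6 of 12 nitrate and peptide transporter genes (1 positive) and 9 of 23 trichome birefringence-like genes (1 positive; median −0.02, mean −0.38, but median 0.06 with the arrays set equal on stable reference genes). Camera called these 6 lists (adjusted p = 3.7e-05, 3.8e-05, 0.0133, 0.00251, 0.025 and 0.0205), at an adjusted p = 0.169, 0.22, 0.169, 0.22, 0.169 and 0.169 with an estimated correlation. AT2G18010 and XTH19 had a larger rise in young hypocotyls (−3.38 ± 0.29 and −3.42 ± 0.40), and the SAUR gene AT3G53250 a fall that was larger in young ones (3.49 ± 0.33).

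Limma called 7962 probe sets (35.0%), 3973 with a positive and 3989 with a negative difference (4618 and 3232 with the arrays set equal on stable reference genes); 2853 differed 2-fold or more. The response was larger in young hypocotyls in 4309 and in mature ones in 3653 of them, and 2438 had fold changes of opposite sign. Without the 4 arrays of low bioC signal the differences of these 7962 had a slope of 0.923 on those of all arrays, and 7960 kept their sign. The 7962 were selected on arrays that this fit reuses, so keeping the sign is partly built in. Of 17 fixed lists 4 were called, and of 35 added lists 11; with an estimated correlation camera called 0, with 3 and 7 at an unadjusted p under 0.05, and fry called 9 and 19.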

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

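The tests without the 4 arrays of low bioC signal were chosen after seeing the data, and those of a common ceiling and of the share of dividing cells after the results they measure had been seen.

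The auxin response differed between ages, by a limma test of the difference itself, in 7962 probe sets. Fixed lists with a called difference had medians of 1.92 for G2/M and cytokinesis, 1.69 for photosynthesis, −1.41 for senescence and −0.39 for cambium regulators. None of these calls holds with an estimated correlation (lowest adjusted p = 0.152), and the cambium call also ends without single arrays (adjusted p = 0.0529, 0.0539 and 0.0501) and without the 4 arrays of low bioC signal (0.119). Added lists with positive differences (a larger rise or a smaller fall in mature hypocotyls) were photosynthesis and photorespiration (1.60), G2/M (1.43), chlorophyll synthesis (1.01), DNA replication (0.66) and cytosolic ribosomal proteins (0.19). Those with negative differences were suberin (−3.69), glutathione S-transferases (−0.71), xylem and secondary wall (−0.66), nitrate and peptide transporters (−0.52), mitochondrion-encoded genes (−0.46) and trichome birefringence-like proteins (−0.0212, where the median changes sign with the scaling). The calls of the added lists are lost with an estimated correlation too (adjusted p between 0.169 and 0.674). Single genes were AT3G46490 (5.16), AT1G09750 (5.04), AT1G71695 (4.78), AT1G12080 (4.53), AT5G48490 (4.21) and GH3.3 (2.11), and with negative values AT4G36430 (−5.30), AT5G12420 (−4.52), AT5G57785 (−4.47), AT4G38080 (−4.33) and AT1G80130 (−4.31).

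Outside the tested genes, the 25S ribosomal RNA control probe set was higher with auxin, by 4.19 ± 0.44 (SE) in young and 3.12 ± 0.44 in mature hypocotyls (log2, n = 3 per group). The rise is smaller against untreated array 3, of usual bioC signal, where this probe set lay at −1.06 at both ages. On the 4 arrays of low signal it lay between −2.56 and −2.19.

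The counts of changed probe sets were set against a batch of arrays marked by the bioC signal. Without the 4 arrays of low signal the fold changes had a slope of 0.984 on those of all arrays in young hypocotyls, 1.02 in mature ones and 0.923 for the difference of the responses, which argues against that batch as the whole cause. For the comparisons of 3 with 3 arrays, 1 of 10 splits gave as many calls as the real one, and 10 splits are too few for a share under 0.05. The real counts were 13440, 13632, 10386 and 6206. The highest other was 0 by limma, where up to 760, 923, 999 and 1616 probe sets had an unadjusted p under 0.05. For age with auxin, where the array numbers pair the arrays by the correlation of deviations alone, the other splits that part all 3 pairs gave 0 as well. In these, up to 812 probe sets had an unadjusted p under 0.05. Every other split mixes the 2 groups and puts their difference into the spread. These counts of 0 therefore decide nothing on chance. For the difference of the responses 2 of 100 splits gave as many as 7962, but this share decides nothing on chance. Splits that mix the auxin labels at both ages put the auxin effect into the spread and gave 0, those that mix them at 1 age still measure the response of the other age (up to 6340), and the highest other (15060) exchanged the labels at 1 age and measures the sum of both responses. Other differences in handling between the treated and untreated arrays stay open, since no label separates them from auxin.

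The fall of photosynthesis genes with auxin kept a median of −6.14 in young hypocotyls without the arrays of low bioC signal, which argues against that batch. Genes induced by darkness or carbon starvation, 5 of 22 listed ones measured, fell with a median of −3.30 in young hypocotyls. For these 5 genes, this argues against carbon starvation during the treatment. The fall does not decide on darkness, since more sugar could lower these genes in the dark too. Their median of −2.19 in mature hypocotyls is consistent with more sugar during the treatment, a medium that the labels do not describe. Whether sugar, another condition of that day or auxin itself lowered these genes stays open, since the design does not separate them.

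The larger response of mitotic genes in mature hypocotyls kept a median difference of 1.56 in the added G2/M list without the arrays of low bioC signal. A common ceiling reached from different starting levels would leave the ages alike with auxin, but the list was higher in mature hypocotyls by a median of 0.76 with 17 of 18 genes past the test, which argues against a ceiling as the whole cause. The median of the DNA replication genes was 0.25 (SD of members 0.10, 6 of 33 listed genes measured), under that of the G2/M genes. This would speak to a larger share of all dividing cells only if replication genes follow that share in this tissue. Whether they do was not tested, so such a share stays open. A difference in cell cycle stage, or in cell types between the ages, stays open too and was not tested.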

How the results depend on the processing

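The fits with a bioC term, those without the 4 arrays of low or the 2 untreated arrays of usual bioC signal and the robust spread estimate were chosen after seeing the data. No named gene reversed where it was called in the main fit or in the alternative. Changes of sign in genes called in neither were not counted. The median of the trichome birefringence-like list in the difference of responses went from −0.02 to 0.06 with stable reference genes set equal. The direction with more calls also changed: with array medians set equal for auxin in mature hypocotyls (7235 higher and 6397 lower to 6632 and 6753), with either scaling for age without auxin (5171 and 5215 to 5233 and 5033 or 4994 and 4932), and with stable reference genes for the difference of responses (3973 and 3989 to 4618 and 3232). For age with auxin it changed at 2-fold or more (3239 and 2967 to 740 and 847). The splits of the other 3 contrasts named here also changed sides under some alternatives that left out arrays or changed the threshold or the fit.

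At least a 2-fold change besides the adjusted p left 5663 probe sets for auxin in young hypocotyls, 5475 in mature ones, 3056 for age without auxin, 1587 for age with auxin, 2853 for the difference of responses and 3755 shared auxin calls, by its construction. Without the 4 arrays of low bioC signal, which leaves 1 array in each untreated group, age without auxin gave 5574 and the difference of responses 4336, and the slope was 0.921; fewer arrays were tested. With the bioC term the counts were 12447, 12547, 10353, 6233 and 7924, in the order of contrasts above. Of 18 same-numbered pairs of arrays 10 deviated together with r above 0.1, and 9 of 12 arrays had their best partner outside the group at their own number. The replicate block gave 13610, 13901, 10634, 6462 and 8213; of the named genes it ended the calls of nad2 for age without auxin and of nad6 and AT2G31110 for age with auxin, and it changed no other call of a named gene or list. Leaving out 1 array gave ranges of 12669 to 13561, 12801 to 13760, 9084 to 10563, 4975 to 6351 and 6982 to 7856, with slopes of 0.864 to 0.887.

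Of the fixed lists, camera with an estimated correlation called 0 in each of the 5 contrasts (3, 2, 3, 1 and 3 at an unadjusted p under 0.05), and fry called 13, 14, 11, 9 and 9. For auxin in young hypocotyls, 4 lists were called with stable reference genes set equal, 4 with the bioC term, 5 without the 4 arrays of low bioC signal and 4 without the 2 of usual signal, and 1 to 4 when 1 array was left out. For age with auxin, 2 were called without the 4 arrays, 2 without the 2 arrays and 0 to 1 without single arrays; for the difference of responses 3 to 4. The cause was not tested. Of 68 called lists in all, fixed and added, 68 lost their call with an estimated correlation, 4 with fry, 4 without the 4 arrays of low bioC signal and 0 with stable reference genes set equal.

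Of 556 results of named genes, 6 lost their call with array medians set equal, 6 with stable reference genes set equal, 14 with the bioC term, 58 without the 4 arrays of low bioC signal and 46 at an adjusted p under 0.01. Quantile normalisation again, filters on dim probe sets and an intensity trend were not run, since the centred values hold no absolute levels. For the same reason signal over background could not be given.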

Other observations

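The test in this part was set before its result was seen, and the distance between groups was added after.

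A hypothesis is that auxin moves young hypocotyls towards the untreated mature state in part of the genes. The young auxin response and the age difference without auxin share the young untreated arrays, which alone makes them covary: their covariance across probe sets was 0.375, against 0.00846 in 100 simulations of unchanged groups that share arrays, a difference of 0.366. Pearson's r was 0.370, and 0.499 in the simulations, where sharing 1 group of pure noise fixes it near that value. The simulations held no real changes, so neither comparison with them decides on the hypothesis. Over all probe sets, the root mean square log2 distance to the untreated mature group was 1.197 after auxin and 0.828 before it. The young group as a whole thus lay further from that state after auxin. A distance over all probe sets does not decide on part of the genes. Any shift common to the 3 young untreated arrays also enters both contrasts, so the hypothesis stays open.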
